A study of Caenorhabditis elegans with 18 samples.

How the data were processed

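Small RNA was sequenced from young adult Caenorhabditis elegans of 6 genotypes with 3 libraries each, 18 libraries in all. Per the labels' protocols, worms were kept on NGM plates with OP50 bacteria at 25 °C, RNA was taken with Trizol, libraries were made with a NEBNext small RNA kit, and a gel band near 140 bp was cut out to select miRNAs. The submitters' processing notes name Bowtie 0.12.7. The genome build and the miRNA annotation are not given in the sources used here, so no coordinates are printed, and the reference annotation (WBcel235) was used only for which miRNA genes lie next to each other.

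The deposited values are expected counts per miRNA, not normalized. Each library lists 176 names and 5 columns, 3 of them numeric, and column 5 is the sum of columns 3 and 4 (largest difference 2.8e-14). What columns 3 and 4 stand for is not stated. Column 4 held at most 0.0031% of the counts of a library. Between 75% and 86.9% of the values of a library were whole numbers at a tolerance of 1e-06, and the rest were fractions, as arise when a read that matches several miRNAs is shared out. Levels of near-identical family members are therefore uncertain. Column 5 was used, and these expected counts were rounded to whole numbers. mir-44 and mir-45 held identical values in all 18 libraries and were summed as mir-44/45, which left 175 miRNAs. Arms of a hairpin are mostly not told apart: only 2 hairpins are named by both arms, so the planned analysis of minor arms was not run.

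Counts were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood test. Scaling used TMM factors, which ranged from 0.876 to 1.1. The filter on low counts (at least 10 counts in the smallest group at the median depth, 15 in total) kept 139 miRNAs. The other 36 miRNAs, 14 of them without a count in any library, held 0.000265% of the counts. All 18 libraries entered the same fit, with genotype as the term, so that 12 residual degrees of freedom estimate the spread, and dispersion and quasi-likelihood fits were robust. The common biological coefficient of variation was 14%. A miRNA is called higher or lower at a Benjamini-Hochberg adjusted p below 0.05. Log2 changes are given with a standard error (SE) taken from the change and its F statistic, and levels as CPM, which are counts scaled by library total and TMM factor, with the SD over 3 libraries. There were 8 contrasts of 2 genotypes and 3 contrasts of differences between the effects of dpf-3 in different backgrounds.

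21 lists of miRNAs were fixed beforehand: families that share a seed, mirtrons, developmental timing miRNAs, ageing and stress miRNAs, and markers of neurons, muscle, intestine, glia and of embryos and oocytes (the mir-35 family). The 15 lists with at least 3 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over 165 tests. Of these tests, 15 passed, 2 passed with an estimated correlation, and 110 passed with fry, which asks a different question (whether a list moves on balance). The share of the mir-35 family was compared by a two-sided exact permutation test, which cannot go below p = 0.1 with 3 libraries against 3. The miRNAs named are the up to 10 largest rises and 10 largest falls per contrast among called miRNAs with a mean of at least 10 CPM and, for contrasts of 2 genotypes, no overlap between the libraries. The 10 most abundant miRNAs of wild type and members of the fixed lists are named too, some are left out for length, and any other is said to have been chosen after its values were seen.

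In data simulated with the wild type means and the real library sizes for the comparison of alg-1 with wild type (139 miRNAs, 20 simulations), 74.0% of 1.5-fold changes, 93.8% of 2-fold changes and 99.5% of 4-fold changes were called in the right direction, and 3.14% of the calls were false. These simulations changed 30 of the 139 miRNAs, fewer than the 117 called in the real comparison, so the rates need not hold where most miRNAs change.

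Replicate numbers are shared between genotypes. Libraries with the same number did not deviate together in every pair, so the numbers were not used as pairs. The labels do not say that replicates were separate cultures, so p-values measure only the spread between these libraries, which may be technical. No 2 libraries of a genotype agreed within sampling noise. The 6 libraries of alg-2 and dpf-3;alg-2 carry a library name label that the other 12 lack, so they may be a separate set. A difference between these 6 and wild type cannot be told apart from a difference between sets. Levels of the dpf-3, alg-1 and alg-2 transcripts are not measured by miRNA counts, so the genotype labels could not be checked on the mutated genes.

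Alternatives fixed before the data were examined were RLE, upper quartile or no composition factors, other low-count filters, DESeq2 1.42.0, limma-voom, fits of the contrast's groups alone, a replicate block over all libraries or within each library set, a required change of 1.5-fold, and each library left out in turn. Added after seeing the data were removal of the mir-35 family before scaling, column 3 alone, and mir-44 and mir-45 as 2 miRNAs.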

Results

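MiRNAs were counted in young adults of wild type, dpf-3, alg-1, dpf-3;alg-1, alg-2 and dpf-3;alg-2 animals, with 3 libraries per genotype. alg-1 and alg-2 encode the main Argonaute proteins that carry miRNAs in C. elegans, and dpf-3 encodes a dipeptidyl peptidase. The design asks how the miRNA profile changes when an Argonaute is lost and whether loss of dpf-3 changes that profile. Totals ranged from 7.78 to 22.5 M (mega) counts per library, with means of 16.9 ± 0.843 M (SD, n = 3) in wild type, 19.4 ± 2.82 in dpf-3, 12.8 ± 1.70 in alg-1, 10.7 ± 2.15 in dpf-3;alg-1, 14.6 ± 3.89 in alg-2 and 12.1 ± 3.72 in dpf-3;alg-2. Between 145 and 154 miRNAs had at least 1 count in a library. In wild type the most abundant were the muscle miRNA mir-1, with 15.1% ± 1.09 of the counts, mir-58 with 10.1% ± 0.523, mir-44/45 with 9.34% ± 0.5001 and mir-71 with 5.85% ± 0.291 (SD, n = 3).

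Libraries of the same genotype were closely alike, with correlations of log2 CPM across miRNAs from 0.995 to 0.999 over 18 pairs, against 0.906 to 0.996 over 135 pairs of different genotypes. The first principal component held 54.2% of the variance and the second 28.7%. The root mean square log2 difference from wild type was 0.81 for dpf-3, 1.96 for alg-1, 0.87 for dpf-3;alg-1, 1.23 for alg-2 and 1.22 for dpf-3;alg-2. Without the mir-35 family it was 0.53, 1.65, 0.81, 0.49 and 0.52.

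The mir-35 family, which is made in oocytes and embryos and is needed for embryonic development, took 12.6% ± 0.916 of the counts in wild type (SD, n = 3). Its share was 2.42% ± 0.680 in dpf-3, 0.339% ± 0.00890 in alg-1, 0.431% ± 0.0555 in alg-2 and 0.453% ± 0.0132 in dpf-3;alg-2. In dpf-3;alg-1 it was 6.23% ± 2.45, with a single library at 9.05% and the others at 4.88% and 4.75%. The 3 libraries of each genotype lay apart from those of wild type, and those of dpf-3;alg-1 lay apart from those of alg-1 and of dpf-3. Each of these differences had an exact permutation p of 0.1, the smallest that 3 against 3 allows, and an adjusted p of 0.114 over 8 comparisons. Embryo and oocyte content was not measured apart from this family. A change in that content therefore cannot be told apart from a change in the miRNAs themselves, in any of the genotypes. dpf-3;alg-2 and alg-2 differed by 0.0224 percentage points, with an exact permutation p of 0.5. That difference was 0.0059 without alg-2 replicate 1, 0.0068 without alg-2 replicate 3 and 0.054 without alg-2 replicate 2, and the difference of 3.81 points between dpf-3;alg-1 and dpf-3 was 2.40 without dpf-3;alg-1 replicate 1.

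**Figure D1:**
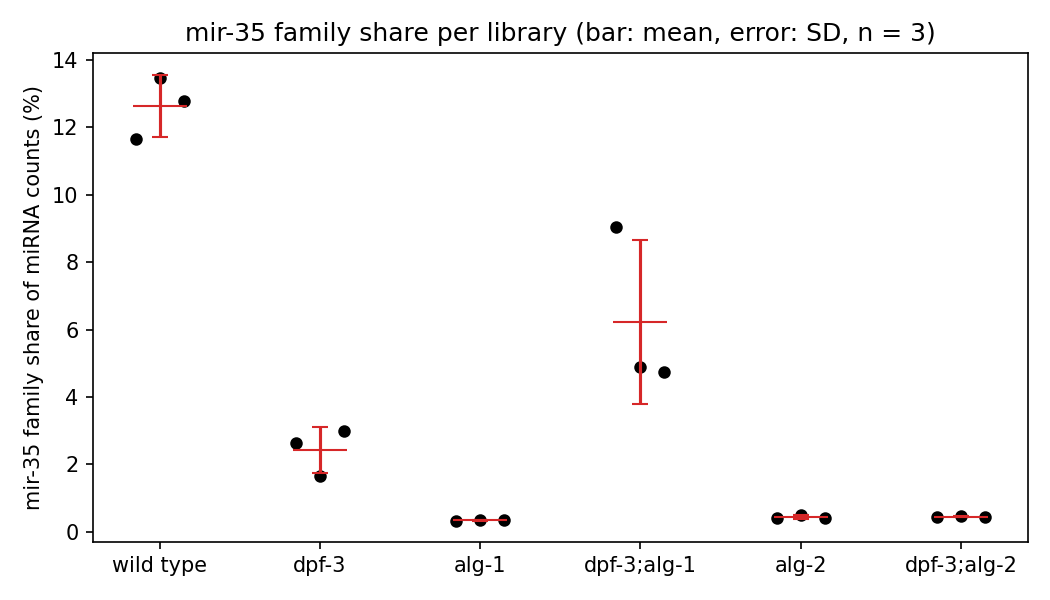
Share of the mir-35 family in all miRNA counts, in percent, for each of the 18 libraries (points), with the mean (bar) and SD (error bar) of the 3 libraries of each genotype. Wild type libraries averaged 12.6%, alg-1 libraries 0.339% and dpf-3;alg-1 libraries 6.23%.

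Loss of dpf-3 alone raised a pair of let-7 family miRNAs and lowered the mir-35 family. mir-48 rose from 20095 ± 1480 to 50958 ± 2743 CPM (SD, n = 3), a log2 change of 1.34 (SE 0.08), and mir-241 rose by 1.70 (SE 0.14). Both act with let-7 in the timing of larval development, and their genes lie next to each other. let-7 itself changed by 0.07 (SE 0.11) and did not pass the test. Of the 8 tested members of the let-7 family 3 were higher and none lower, mir-48, mir-241 and mir-795, with mir-795 at 0.47 (SE 0.17). Of the 6 developmental timing miRNAs 4 were higher, also 4 when adjusted over the list alone, with mir-237 at 0.41 and lin-4 at 0.28. All 8 members of the mir-35 family were lower, from -1.16 (SE 0.39) for mir-42 to -3.41 (SE 0.45) for mir-38. The call of mir-42 was lost with a replicate block over all libraries. mir-788 rose from 17.5 ± 2.95 to 73.3 ± 36.1 CPM, mir-70 rose by 0.67 (SE 0.11) and mir-244 by 0.91 (SE 0.18), while mir-253 fell by 1.26 (SE 0.18) and mir-43, which lies next to mir-42, fell by 1.11 (SE 0.17).

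In all, 22 of 139 miRNAs were higher and 25 lower in dpf-3 than in wild type by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 6 and 12 of them by at least 2-fold. The libraries of the genotypes did not overlap for 46.0% of the miRNAs, where chance gives 10%. The mir-35 family passed camera with an adjusted p of 1.4e-09 (0.11 with an estimated correlation) and the developmental timing list with 0.0030 (0.11 with an estimated correlation). Markers of neurons, muscle and intestine had no called member, and the glia marker mir-228 rose by 0.43 (SE 0.13). Scaling moved the split of calls to 15 higher and 27 lower with RLE, 32 and 20 with no composition factor, and 57 and 11 with upper quartile factors, which shifted the median of all miRNAs from 0.02 to 0.33. The calls of mir-42, mir-795, lin-4 and mir-228 were each lost when some single library was left out.

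Loss of alg-1 changed most of the profile. mir-85 fell from 7989 ± 748 to 264 ± 16.5 CPM (SD, n = 3), a log2 change of -4.92 (SE 0.14). mir-246, a miRNA linked to ageing, fell by 4.56 (SE 0.18) and mir-1817 fell from 55.3 ± 9.35 to 1.33 ± 0.220 CPM. let-7 fell by 1.43 (SE 0.11), mir-359 by 3.72 (SE 0.20), and mir-240 and its neighbour mir-786 by 2.65 and 2.62. The mirtron mir-1020, made by splicing, fell by 2.91 (SE 0.14). Among the rises, mir-797 went from 9.01 ± 2.50 to 114 ± 10.5 CPM and mir-247 from 41.1 ± 6.54 to 305 ± 19.7 CPM. mir-244 rose by 2.68 (SE 0.19), mir-251 by 2.66 (SE 0.20), mir-83 by 1.95 (SE 0.10) and mir-53 by 1.74 (SE 0.11).

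By group, 7 of 8 mir-35 family members were lower in alg-1, from -4.31 for mir-38 to -5.90 for mir-37, and mir-42, at 0.35 (SE 0.39), did not pass. The let-7 family was divided, with 3 members higher (mir-793, mir-48 and mir-1821) and 4 lower (let-7, mir-241, mir-84 and mir-794), of which mir-241, mir-84 and mir-794 turned to higher with upper quartile factors. The calls of mir-794 and mir-1821 were lost without wild type replicate 2 or without wild type replicate 3. All 4 members of the mir-2 family rose, by 0.79 to 3.66, as did all 3 of the mir-44 family. In the mir-51 family 4 of 6 were higher and mir-55 was lower. All 5 of the mir-64 family were lower, mir-64 and mir-65 by more than 2 log2 units (-2.10 and -2.21), and mir-63, mir-66 and mir-229 turned to higher with upper quartile factors. Markers of other tissues moved as well. All 5 neuron markers were higher, from 0.65 (SE 0.12) for mir-793 to 2.02 (SE 0.16) for mir-791, and the glia marker mir-228 rose from 5664 ± 413 to 21139 ± 2200 CPM. The intestine marker mir-60 rose by 0.65 (SE 0.11), while the other intestine marker, mir-243, was at 298 ± 48.7 CPM against 372 ± 20.8 in wild type. The muscle marker mir-1, at -0.02 (SE 0.10), did not pass.

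59 of 139 miRNAs were higher and 58 lower in alg-1 than in wild type (edgeR, adjusted), 38 and 35 of them by at least 2-fold. The mir-35 family was the only list past camera in this comparison, with an adjusted p of 0.013, which was 0.76 with an estimated correlation. With upper quartile factors 94 were higher and 25 lower, and the median of all miRNAs moved from -0.08 to 1.07.

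Loss of dpf-3 in alg-1 animals moved most of these miRNAs back. Compared with alg-1, mir-85 in dpf-3;alg-1 rose by 4.91 (SE 0.14) to 7929 ± 910 CPM (SD, n = 3), mir-246 by 4.95 (SE 0.19) to 6343 ± 1394 CPM and mir-1817 by 5.07 (SE 0.23). mir-35 rose by 4.84 (SE 0.31), mir-359 by 3.41 (SE 0.19), mir-786 by 3.09 (SE 0.15) and let-7 by 1.91 (SE 0.11). mir-788 fell from 43.9 ± 1.07 to 4.61 ± 2.34 CPM. mir-797 fell by 2.76 (SE 0.34), mir-244 by 2.71 (SE 0.19), mir-43 by 2.48 (SE 0.17), mir-227 by 2.11 (SE 0.13) and mir-228 by 1.61 (SE 0.13). Of the mir-35 family 7 members rose and mir-42 fell by 1.55 (SE 0.40). 5 of 8 let-7 family members and 4 of 5 mir-64 family members rose, while all 4 of the mir-2 family and all 3 of the mir-72 family fell. With upper quartile factors the rises of mir-84, mir-794, mir-63 and mir-66 turned to falls. Among neuron markers mir-124 and mir-791 fell, and the other 3 did not pass.

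48 miRNAs were higher and 58 lower in dpf-3;alg-1 than in alg-1 (edgeR, adjusted). With upper quartile factors the split was 22 and 101, and the median of all miRNAs moved from -0.14 to -1.27. The mir-35 family passed camera with an adjusted p of 0.036, which was 0.78 with an estimated correlation. Of the 58 miRNAs lower in alg-1 than in wild type, 46 were higher in dpf-3;alg-1 than in alg-1 and 2 were lower. Of the 59 higher ones, 49 were lower and none was higher by the adjusted test. Because both comparisons use the alg-1 libraries, data were simulated with no return, that is, with dpf-3;alg-1 at the alg-1 means. There, at most 1 miRNA went back per direction in 30 simulations. Across the 139 miRNAs, which are not independent replicates, the slope of the second change on the first was -0.75 when different alg-1 libraries served each change, against -0.035 to 0.024 in 200 simulations with no return. The covariance was -2.85, against -0.136 to 0.0947.

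**Figure D2:**
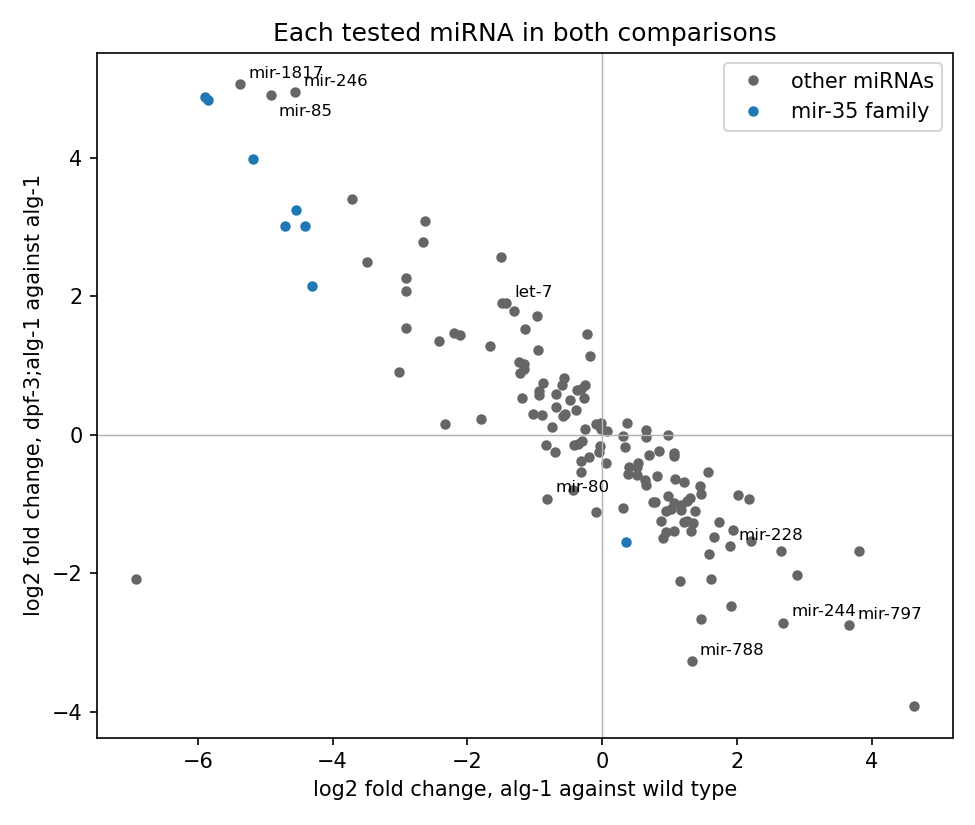
Log2 fold change of each of the 139 tested miRNAs in alg-1 against wild type (horizontal axis) and in dpf-3;alg-1 against alg-1 (vertical axis), with the mir-35 family in blue. Most points fall along a descending diagonal, from mir-1817 at -5.37 and 5.07 to mir-797 at 3.66 and -2.76, while mir-42 of the family lies at 0.35 and -1.55 and the point far left, mir-799, rests on 1 count in alg-1 and 0 in dpf-3;alg-1.

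dpf-3;alg-1 animals still differed from wild type. mir-784 stayed low, at 5.77 ± 0.270 CPM against 25.0 ± 2.03 in wild type (SD, n = 3), a log2 change of -2.11 (SE 0.14). mir-355 was lower by a log2 change of -1.58 (SE 0.14). mir-80, a member of the mir-58 family, was at 13464 ± 1257 CPM against 45020 ± 9827 CPM and was also lower than in alg-1, by a log2 change of -0.92 (SE 0.17). All 3 tested mirtrons were lower, mir-1020 at -1.36 (SE 0.13), mir-62 at -1.23 (SE 0.12) and mir-1018 at -0.85 (SE 0.20). All 8 members of the mir-35 family were lower than in wild type, from -1.004 (SE 0.26) for mir-35 to -2.16 (SE 0.42) for mir-38. 7 of 8 let-7 family members were higher, with mir-795 at 1.23 (SE 0.17), mir-241 at 0.74 (SE 0.14) and let-7 at 0.48 (SE 0.11). mir-250 and its neighbour mir-61 were higher by 1.03 (SE 0.11) and 0.97 (SE 0.11), and mir-253 by 1.08 (SE 0.18). 4 of 5 neuron markers were higher, mir-791 by 1.15 (SE 0.16) and lsy-6 by 0.81 (SE 0.18). mir-799, chosen after its values were seen, had 223 counts in the wild type libraries together, 1 in alg-1 and 0 in dpf-3;alg-1. That is 169-fold lower in alg-1 (95% counting interval 29.97 to 6693) and at least 47.0-fold lower in dpf-3;alg-1, against a floor of 3 counts over the group. Such intervals and floors cover counting error only.

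36 miRNAs were higher and 43 lower in dpf-3;alg-1 than in wild type (edgeR, adjusted), 5 and 19 of them by at least 2-fold. With the mir-35 family removed, the split was 42 and 29. The let-7 family passed camera with an adjusted p of 0.012 (0.58 with an estimated correlation) and the mirtrons with 0.033 (0.32 with an estimated correlation). Against dpf-3, 40 miRNAs were higher and 41 lower, or 19 and 56 with upper quartile factors, which moved the median from -0.0032 to -0.27. mir-253 rose by 2.34 (SE 0.18) and 7 of 8 mir-35 family members rose by 1.09 to 1.52, of which the calls of mir-38 and mir-41 were lost without dpf-3;alg-1 replicate 1. mir-788 fell by 4.01 (SE 0.45), mir-784 by 2.05, mir-80 by 1.90, mir-227 by 1.28 and the mirtron mir-62 by 1.40. Of the 3 let-7 family members raised in dpf-3, mir-241 and mir-48 fell by 0.96 (SE 0.14) and 0.80 (SE 0.08) on the log2 scale between dpf-3 and dpf-3;alg-1, and mir-795 rose by 0.77 (SE 0.17).

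**Figure D3:**
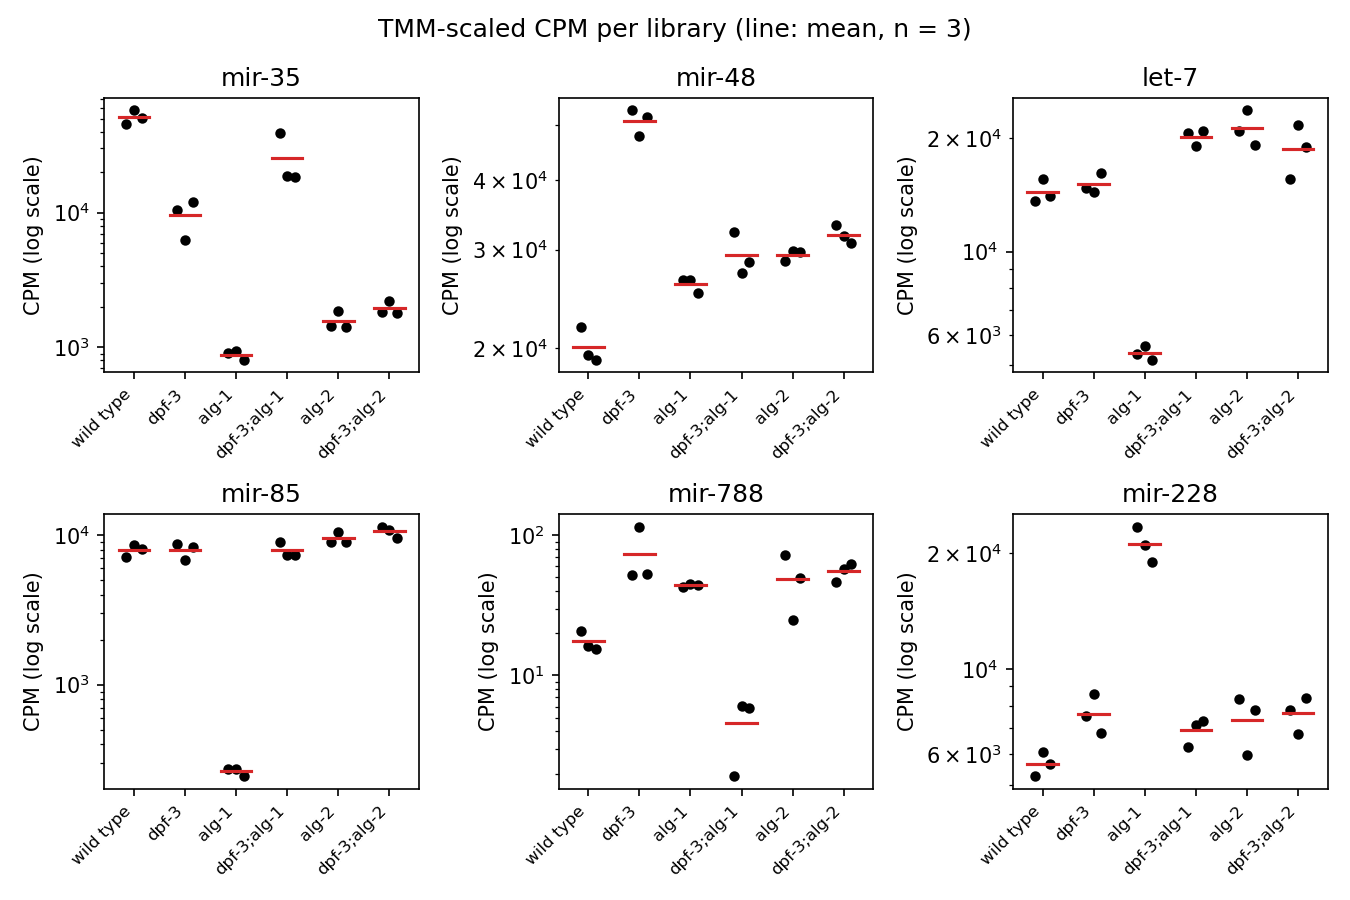
TMM-scaled CPM of 6 miRNAs in each library (points, log scale) by genotype, with the mean of 3 libraries (line). mir-85 was at 264 CPM in alg-1 and 7929 CPM in dpf-3;alg-1, and mir-48 was highest in dpf-3, at 50958 CPM.

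In alg-2 animals the main change was the fall of the mir-35 family. All 8 members were lower than in wild type, 7 of them with log2 changes from -4.64 to -5.79, and mir-42 fell by 1.47 (SE 0.40). mir-35 went from 50948 ± 6079 to 1568 ± 243 CPM (SD, n = 3). All 6 developmental timing miRNAs were higher, with mir-237 at 0.86 (SE 0.09), mir-241 at 0.63 (SE 0.14) and let-7 at 0.56 (SE 0.11). mir-78 rose from 25.95 ± 7.56 to 71.1 ± 24.7 CPM and mir-788 by 1.49 (SE 0.39), and mir-253 fell by 1.01 (SE 0.18). Of the neuron markers 1 of 5 was higher, mir-790 at 0.54, while mir-124, at -0.38 (SE 0.16), did not pass. The glia marker mir-228 and the muscle marker mir-1 were both higher by 0.38, and the calls of mir-790 and mir-228 were lost without alg-2 replicate 1 or without alg-2 replicate 3. These libraries and the wild type libraries differ in the library name label, so genotype and library set cannot be told apart here.

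37 miRNAs were higher and 26 lower in alg-2 than in wild type (edgeR, adjusted), 2 and 13 by at least 2-fold. The count of higher miRNAs was 23 without alg-2 replicate 1 and 23 without alg-2 replicate 3. With upper quartile factors 104 were higher and 7 lower, and the median moved from 0.06 to 0.87. The mir-35 family passed camera with an adjusted p of 5.5e-21 (0.0047 with an estimated correlation) and the timing list with 0.019 (0.25 with an estimated correlation).

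Loss of dpf-3 in alg-2 animals changed few miRNAs. None of the 8 mir-35 family members and none of the 6 developmental timing miRNAs passed the edgeR test between dpf-3;alg-2 and alg-2. mir-48 changed by 0.12 (SE 0.08) and mir-241 by 0.17 (SE 0.14). mir-62 rose from 163 ± 10.99 to 285 ± 26.4 CPM (SD, n = 3), and the other mirtron that passed, mir-1018, rose by 0.81 (SE 0.19), a call lost without dpf-3;alg-2 replicate 3. mir-355 rose by 0.78 (SE 0.14), mir-244 by 0.76 (SE 0.18), mir-246 by 0.72 (SE 0.16) and mir-786 by 0.63 (SE 0.14). mir-78 fell by 1.76 (SE 0.29), the neuron marker mir-790 by 1.002 (SE 0.21) and mir-34, a miRNA linked to stress responses, by 0.53 (SE 0.12). The other neuron markers did not pass. 18 miRNAs were higher and 8 lower, or 16 and 14 with RLE factors. The count of lower miRNAs was 5 without alg-2 replicate 1, without alg-2 replicate 3 or without dpf-3;alg-2 replicate 2. The slope of the change from alg-2 to dpf-3;alg-2 on the change from wild type to alg-2 was -0.041. That lies inside the -0.064 to 0.084 of simulations with no return, but it was -0.075, past them, without alg-2 replicate 2. Without the mir-35 family it was -0.21, outside the -0.136 to 0.135 of those simulations. Of the 37 miRNAs higher in alg-2 than in wild type, 6 were lower in dpf-3;alg-2 than in alg-2 and 1 was higher. Of the 26 lower ones, 6 were higher and 0 lower. In 30 simulations with no return, at most 0 and 1 went back.

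Against wild type, dpf-3;alg-2 had 40 miRNAs higher and 26 lower, or 29 and 30 with RLE and 111 and 7 with upper quartile factors, which moved the median from 0.10 to 0.96. The count of lower miRNAs was 17 without wild type replicate 3. All 8 mir-35 family members were lower, mir-38 by the most (-5.31, SE 0.50), and all 6 developmental timing miRNAs were higher, with mir-237 at 0.91 (SE 0.09), mir-241 at 0.80 (SE 0.14) and mir-48 at 0.67 (SE 0.08). mir-788 was higher by 1.66 (SE 0.39) and mir-244 by 1.22 (SE 0.18), and mir-43 was lower (-1.25, SE 0.18). The family passed camera with an adjusted p of 1.5e-20 (0.0047 with an estimated correlation) and the timing list with 0.036 (0.32 with an estimated correlation). The call of let-7 was lost without dpf-3;alg-2 replicate 2. This comparison crosses the library sets as well.

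The calls of alg-1 and dpf-3, each against wild type, overlapped about as often as independent lists would. 8 miRNAs were higher in both and 12 lower in both, where independent lists give 9.34 and 10.4, and 5 were higher in both without wild type replicate 1 or without wild type replicate 3. With upper quartile factors many more were higher in both, and with a required change of 1.5-fold fewer were, as given below. 7 of the 12 were mir-35 family members, as 5 were left without the family, where independent lists give 6.62, and the 8 higher in both compare with 9.91. 11 were higher in alg-1 and lower in dpf-3, and 11 were lower in alg-1 and higher in dpf-3. Across miRNAs the correlation of log2 changes was 0.40 (covariance 0.657), and 0.020 without the mir-35 family (covariance 0.0190). The 3 wild type libraries serve both comparisons and cannot be split between them. Unchanged groups simulated against the same wild type libraries gave a mean correlation of 0.50 (0.27 to 0.68), a mean covariance of 0.0193 and no shared calls in 100 simulations. Such groups hold no changes, so a lack of shared calls was fixed in advance. Their correlation is that of noise with shared controls and sets no level for the real correlation of 0.40.

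The effect of losing dpf-3 differed between backgrounds by the tests of the difference itself. The mir-35 family was lower in dpf-3 than in wild type, while 7 of its 8 members were higher in dpf-3;alg-1 than in alg-1. The differences between these effects were 7.41 for mir-37 and 7.26 for mir-35. Embryo content of the animals was not measured and may differ between the genotypes. The differences were -5.34 for mir-788 and -3.62 for mir-244. In alg-2 animals no family member passed the test for an effect of dpf-3, and the difference from the effect in otherwise wild type animals was positive for 7 of 8 members, such as mir-41 (3.58, from a change of -2.77 without the alg-2 mutation and 0.81, not past the test, with it). It was negative for mir-241 (-1.53) and mir-48 (-1.22). The mir-35 family was already at 0.431% of the counts in alg-2, below the 2.42% in dpf-3. Its members there ranged widely, with mir-35 still at 1568 CPM and mir-41 at 1.40 CPM. Whether the low level limits a further fall was not tested. Between alg-1 and alg-2 animals the effect differed by 4.76 for mir-85 and 4.998 for mir-1817.

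By edgeR's quasi-likelihood test with adjustment, 40 differences were positive and 56 negative between alg-1 animals and otherwise wild type animals, or 15 and 104 with upper quartile factors, which moved the median from -0.23 to -1.67. For alg-2 they were 23 and 16, or 10 and 33 with upper quartile factors (median from 0.04 to -0.22), 14 and 24 with no composition factor, and 13 and 21 without the mir-35 family. These alg-2 counts were 13 and 5 without wild type replicate 1, and the negative count was 6 without alg-2 replicate 1, 10 without alg-2 replicate 3 and 9 without dpf-3;alg-2 replicate 2. Between alg-1 and alg-2 animals they were 43 and 49, or 18 and 96 with upper quartile factors (median from -0.17 to -1.34). The mir-35 family passed camera in the 3 contrasts, with adjusted p of 3.5e-05, 3.2e-09 and 0.035 (0.37, 0.11 and 0.78 with an estimated correlation). In the alg-2 contrast the developmental timing list passed with 0.0027 (3 of 6 lower, 4 adjusted over the list alone) and the let-7 family with 0.021 (3 of 8 lower), and these were 0.11 and 0.67 with an estimated correlation.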

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

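The contrasts, the differences of effects among them, belong to the main analysis, and the lists and most alternatives were fixed beforehand. The other tests below were chosen after the results they bear on had been seen. Groups of 3 libraries were not tested for outlying libraries. The values that follow differ between genotype backgrounds by a test of the difference itself (edgeR, adjusted).

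The effect of losing dpf-3 in alg-1 animals, less the effect in otherwise wild type animals, was positive for 40 miRNAs and negative for 56. Among called miRNAs with a mean of at least 10 CPM, the largest log2 differences were mir-37 (7.41), mir-35 (7.26), mir-40 (6.31), mir-36 (5.81) and mir-41 (5.80). In the other direction they were mir-788 (-5.34), mir-244 (-3.62), mir-797 (-3.17), mir-247 (-2.80) and mir-227 (-2.44). Of 100 splits of the libraries 3 gave as many calls, where the real one gave 96 and the highest other 96, and all 3 keep the real labels of the alg-1 background. For alg-2 the difference was positive for 23 miRNAs and negative for 16 (13 and 5 without wild type replicate 1, and 6, 10 and 9 negative without alg-2 replicate 1, alg-2 replicate 3 and dpf-3;alg-2 replicate 2), with mir-41 (3.58), mir-39 (2.83), mir-38 (2.74), mir-35 (2.73), mir-36 (2.63), mir-78 (-2.16), mir-788 (-1.90), mir-241 (-1.53), mir-48 (-1.22) and mir-1819 (-1.02). There 2 of 100 splits gave as many, with 39 in the real one and 42 in the other, which keeps the alg-2 background and swaps dpf-3 with wild type. In alg-2 the mir-35 family was already at 0.431% of the counts, and whether that level limits a further fall was not tested. The call of mir-788 in this contrast was lost without alg-2 replicate 1. Between alg-1 and alg-2 animals it was positive for 43 miRNAs and negative for 49, with mir-37 (5.06), mir-1817 (4.998), mir-85 (4.76), mir-35 (4.53), mir-246 (4.23), mir-244 (-3.47), mir-788 (-3.44), mir-797 (-2.65), mir-227 (-2.49) and mir-43 (-2.18). There 10 of 100 splits gave as many as the real 92, the highest other 103, and all 10 keep the real labels of the alg-1 background. Splits that keep a background's labels still hold the effect of dpf-3 there, and they are 20 of the 200 possible, so these counts do not measure chance for a difference of effects and whether it can be excluded is left open.

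For the 8 comparisons of 2 genotypes there are 10 splits, too few for a share under 0.05. The real split was the only 1 of 10 with as many calls. The real counts were 47 for dpf-3, 117 for alg-1, 79 for dpf-3;alg-1, 63 for alg-2 and 66 for dpf-3;alg-2 against wild type, 106 for dpf-3;alg-1 against alg-1, 81 for dpf-3;alg-1 against dpf-3 and 26 for dpf-3;alg-2 against alg-2, and the highest other was 0 in each.

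28 miRNAs outside the mir-35 family were at least 2-fold lower in alg-1, with a median log2 change of -2.26. If the mir-35 family marks embryo content alike in both genotypes, fewer embryos and oocytes would lower them in alg-2 as well. The family was as low there (median -4.90, against -4.62 in alg-1). In alg-2 their median was 0.047 (quartiles -0.22 to 0.46), and 27 of 28 changed by less than 50% as much. That argues against fewer embryos and oocytes only if the fall of the family reflects embryo content in both genotypes, which was not measured. mir-42 of the family was lower in alg-2 but not in alg-1 (0.35, not past the test). A further limit is that alg-2 and wild type differ in library set. Counts freed by the loss of the mir-35 family are argued against by the size of the family, 12.6% of the wild type counts. With the family removed before scaling, 108 of 110 calls outside it were kept. TMM factors already allow for such a shift, so that count adds little. It does not bear on other shifts of scale, such as the median shift of 1.16 with upper quartile factors. A difference due to the loss of alg-1 may be the cause and stays a hypothesis, untested beyond these values. A difference in the stage of the alg-1 animals was not measured and stays open too.

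The return toward wild type in dpf-3;alg-1 had a slope of -0.7506 with disjoint alg-1 libraries, below all 200 simulations with no return (lowest -0.035), which argues against noise shared through those libraries. The simulations gave dpf-3;alg-1 the alg-1 means, so they cannot tell a return to wild type from a move toward another profile. Without the mir-35 family, the root mean square log2 difference of dpf-3;alg-1 was 0.81 from wild type, 0.94 from dpf-3, 0.90 from alg-2 and 1.455 from alg-1. A mixture of wild type, dpf-3 and alg-1 would place few miRNAs beyond all 3 at once, and 15 of 139 miRNAs (10.8%) lay there, 7 above and 8 below, against a limit of 5% and at most 0 in 50 simulated mixtures, which argues against it. Of those above, mir-794 turned to lower than in alg-1 with upper quartile factors. These factors also shifted the comparison with dpf-3 by a median of -0.26. Smaller rises over dpf-3, such as let-7 at 20147 against 15098 CPM, therefore depend on the scaling. How many of the 7 stay past the threshold with these factors was not counted. Libraries of alg-2 or dpf-3;alg-2 are argued against by mir-799, with 0 counts where 246.7 and 199.4 are due at their rates, since wild type and dpf-3 of the same library set as dpf-3;alg-1 hold 223 and 412 counts. Genotypes outside the series have no library here and stay open, as does a joint effect of losing dpf-3 and alg-1, which may underlie the return and is a hypothesis. The stage of the animals beyond young adult was not measured, so a difference in stage or gonad particular to alg-1 stays open as well.

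The mir-35 family was lower in alg-2 and dpf-3;alg-2 than in wild type, with a median of -4.902 in alg-2. These genotypes carry the library name label and wild type does not, so genotype and library set cannot be told apart. None of the 18 libraries is a wild type library with that label. A difference in embryo content of the animals was not measured apart from the family itself.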

How the results depend on the processing

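The 3 alternatives added after seeing the data were removal of the mir-35 family, column 3 alone, and mir-44 and mir-45 as 2 miRNAs. With upper quartile factors, higher and lower calls became 57 and 11 for dpf-3, 94 and 25 for alg-1, 104 and 7 for alg-2 and 111 and 7 for dpf-3;alg-2 against wild type, 22 and 101 for dpf-3;alg-1 against alg-1, and 19 higher for dpf-3;alg-1 against dpf-3. For dpf-3;alg-2 against alg-2 5 were lower, the differences of effects gave 15 and 104 (alg-1), 10 and 33 (alg-2) and 18 and 96 (alg-1 against alg-2), and the overlap gave 39 higher and 7 lower in both. Single miRNAs were followed across the alternatives only if among the largest rises and falls, the 10 most abundant, or members of some fixed lists. Other called miRNAs with changes smaller than the upper quartile shift and opposite in sign would turn as well. Among those followed, directions turned for 37 called values, all with upper quartile factors. They were, in dpf-3 against wild type, mir-66 0.048 and mir-229 0.049. In alg-1 they were mir-84 0.90, mir-241 0.19, mir-794 0.91, mir-80 0.34, mir-63 0.49, mir-66 0.48, mir-229 0.43, mir-62 0.73 and mir-237 0.85. In dpf-3;alg-1 against alg-1 they were mir-84 -0.60, mir-794 -0.41, mir-81 -0.091, mir-63 -0.72, mir-66 -0.54 and mir-237 -0.46. In alg-2 they were mir-66 0.40, mir-229 0.44, mir-1018 0.32 and mir-71 0.17, and in dpf-3;alg-2 against wild type mir-66 0.46, mir-229 0.47, mir-1020 0.40, mir-124 0.40 and mir-71 0.25. In the difference for alg-1 they were mir-84 -0.98, mir-794 -0.74, mir-795 -0.43, mir-81 -0.21, mir-63 -0.94, mir-66 -0.59 and mir-229 -1.06, and between alg-1 and alg-2 mir-84 -0.59, mir-81 -0.47, mir-66 -0.60 and mir-237 -0.56. These factors moved the miRNAs of a comparison by about the same amount, except for at most 2 of 139 that lay over 0.1 from the median shift, mir-799 the farthest. The median shift was 1.16 in alg-1 against wild type (5th to 95th percentile 1.15 to 1.17), -1.12 in dpf-3;alg-1 against alg-1 and 0.81 in alg-2 against wild type, so a turned direction says nothing of that miRNA apart from the others. The stricter filter, which tests fewer miRNAs, gave 14 higher in dpf-3, 19 in alg-2 and 25 in dpf-3;alg-2, 5 lower in dpf-3;alg-2 against alg-2 and 5 higher in both of the overlap. A required change of 1.5-fold gave 12 higher in dpf-3, 19 in dpf-3;alg-1, 10 in alg-2 and 17 in dpf-3;alg-2 against wild type, 25 in dpf-3;alg-1 against dpf-3, 3 lower in dpf-3;alg-2 against alg-2 and 3 higher in both of the overlap. Without the mir-35 family 14 were lower in dpf-3, 14 in dpf-3;alg-2 against alg-2, 13 differences for alg-2 were positive, 5 were lower in both of the overlap, and the return in dpf-3;alg-2 was -0.2087, beyond its simulations. RLE and DESeq2 each gave 14 lower in dpf-3;alg-2 against alg-2, no composition factor gave 14 positive differences for alg-2, and the 2 groups alone gave 20 higher in alg-2; the cause was not tested. Without the most abundant miRNA the share of the mir-35 family differed from wild type by -11.95 points in dpf-3, -14.49 in alg-1, -14.34 in alg-2 and -14.32 in dpf-3;alg-2, as its total is smaller. Of the 165 tests of lists, 2 passed with an estimated correlation and 110 with fry. With each library left out in turn, the ranges were 23 to 44 higher in alg-2 (23 without alg-2 replicate 1 or 3), 5 to 9 lower in dpf-3;alg-2 against alg-2 (5 without alg-2 replicate 1 or 3 or dpf-3;alg-2 replicate 2), 17 to 25 lower in dpf-3;alg-2 against wild type (17 without wild type replicate 3), 13 to 24 positive and 5 to 21 negative differences for alg-2 (13 and 5 without wild type replicate 1, 6 and 10 negative without alg-2 replicate 1 and 3, 9 without dpf-3;alg-2 replicate 2), -0.07544 to -0.01944 for the return in dpf-3;alg-2 (past its simulations without alg-2 replicate 2) and 5 to 7 higher in both of the overlap (5 without wild type replicate 1 or 3). The other counts stayed within 1.5 times. The return in dpf-3;alg-1 ranged from -0.7742 to -0.7093. Libraries with the same replicate number correlated from -0.41 to 0.44 over the 8 comparisons. A replicate block gave 20 higher and 21 lower in dpf-3, and a block within each library set 21 and 24. Neither moved a count by over 1.5 times, and the latter gave no value for alg-2 or dpf-3;alg-2 against wild type. The block over all libraries ended the calls of mir-42 and mir-66 in dpf-3, mir-794 in alg-1, mir-797 in dpf-3;alg-1 against wild type, lin-4 in dpf-3;alg-1 against dpf-3, mir-790 and mir-1018 in alg-2, mir-52 in dpf-3;alg-2 against alg-2, and mir-58 and mir-82 among the differences of effects, and the block within sets ended 9 calls. For mir-799, depth limits the size of the fold bound in dpf-3;alg-1, where 141 counts would be present at the wild type rate and 0 were found.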

Other observations

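Several miRNAs in dpf-3;alg-1 lay outside the range of wild type, dpf-3 and alg-1. mir-253 was at 708 ± 95.2 CPM against 335 ± 11.4 in wild type, 140 ± 11.9 in dpf-3 and 119 ± 6.28 in alg-1 (SD, n = 3). mir-227 was at 237 ± 7.15 CPM against 460 ± 14.9, 578 ± 26.3 and 1022 ± 117. Also above all 3 were let-7, mir-246, mir-786, mir-794, mir-795 and mir-2953-3p, and also below all 3 were mir-49, mir-62, mir-79, mir-80, mir-243, mir-788 and mir-1018, each past the edgeR threshold in all 3 comparisons and chosen after its values were seen. With upper quartile factors mir-794 turned to lower than in alg-1, and the smaller rises over dpf-3, such as that of let-7, depend on the scaling.

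Other fixed families moved in alg-1 as follows. In the lin-4 family lin-4 rose by 0.52, and mir-237 fell by 0.31 and turned to higher with upper quartile factors. In the mir-50 family mir-90 rose by 1.47, while mir-50 fell by 1.24 and mir-62 fell by 0.43, the last turning to higher with upper quartile factors. In the mir-58 family mir-58 rose by 0.69, while mir-81 and mir-82 were at -1.16 and -1.67 and mir-80, at -0.82, turned to higher with upper quartile factors. In the mir-72 family mir-72 rose by 1.30 and mir-74 by 0.76. Both mir-75 and mir-79 of the mir-75 family rose. In the mir-87 family mir-233 rose by 1.27 and mir-356 fell by 0.38. In the mir-238 family mir-238 rose by 0.40 and mir-239a by 1.03, and in the mir-232 family mir-232 rose by 1.59 and mir-357 fell by 0.95. The falls of mir-356 and mir-357 were smaller than the median shift of 1.16 with upper quartile factors, but their directions there were not followed. Of the 6 ageing and stress miRNAs 3 were higher in alg-1 (mir-34, mir-238 and mir-239a) and mir-246 was lower. In dpf-3, mir-34 fell by 0.67 and mir-71 by 0.69, the call of mir-71 being lost without wild type replicate 1. None of these lists with at least 3 tested members passed camera. The lin-4, mir-75 and mir-232 families have fewer members and were not tested with it.

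A hypothesis tested after the values were seen is that miRNA genes of different families lying next to each other change together. Over 16 pairs within 10 kb (128 of 139 names matched in WBcel235), the mean absolute log2 difference between neighbours in alg-1 was 0.7785, against 2.19 for random relabellings (permutation p 5.0e-05). In dpf-3 it was 0.282 against 0.772 (permutation p 9.0e-04). The relabellings drew on all 139 miRNAs, mir-35 to mir-41 among them, though these are in none of the pairs. Their large falls raise the random mean, so the permutation p-values do not decide whether neighbours change together. Pairs with similar changes in alg-1 are mir-240 with mir-786 and mir-247 with mir-797. Neighbours that moved apart there were mir-80 and mir-238 (-0.82 and 0.40), mir-2 and mir-71 (0.79 and -0.35), and mir-2220 and mir-1018 (0.31 and -0.31). Others differed in size, such as mir-792 and mir-1821 (2.22 and 0.35) and mir-42 and mir-43 (0.35 and 1.92). These pairs were chosen after their values were seen. Shared transcripts may contribute where neighbours change alike, and the data hold no measure of precursors.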
